A study of Mus musculus with 2 samples.

How the data were processed

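Poly(A)-enriched RNA of cultured neural stem cells from embryonic day 12 mice of the ICR strain was sequenced, per the labels, after 1 day in proliferation medium and infection with lentivirus. Neural stem cells are the dividing precursors of neurons and glia. There were 2 libraries, 1 that carried the Piscor construct, which the series title calls the control, and 1 that carried the construct Nap1l1-shRNA1. A short hairpin RNA (shRNA) is a small folded RNA made to lower the mRNA of the gene it matches. Nap1l1 encodes nucleosome assembly protein 1-like 1, a histone chaperone. The column of the control writes its name with i and s exchanged against the sample title, and was matched to that title.

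Per the submitters' processing notes, TopHat2 2.0.12, Bowtie 1.0.1 and HTSeq 0.6.0 were used. The notes used here give no role for each tool, no genome build and no strand setting. The authors deposited raw read counts per Ensembl gene for both libraries, per the file headers. The deposited normalized values are CPM (counts scaled to the library total): each is the count times 1 step per library, and the library total that each step implies is a whole number within the rounding of the deposited decimals, 8777836 for the shRNA library and 8325166 for the control. These were taken as the library totals. The deposited fold change is the ratio of these CPM values, recomputed here to within 7.18e-08 of its size in every row. The deposited log2 fold change takes a control count of 0 as 0.5 counts, while the deposited fold change takes it as 0.0285 counts (0.00342 CPM). The deposited p-values and adjusted p-values compare 1 library with 1 library, and the test behind them is not given in the sources used here. The design text gives the authors' selection as p under 0.05 and an absolute log2 fold change above 1.

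The table holds 158 genes, and all 158 are marked up. Every listed gene has a deposited p of 0.0457 or less and a deposited log2 fold change of 1.01 or more. Part of the authors' comparison is thus not analysed here. A multiplier of 17889.1 was found by searching for the value that brought the ranks below closest to whole numbers in these same data. It is not a whole number, so it was not read as a number of genes tested. For 48 of the 59 distinct p-values, p times 17889.1 divided by the adjusted p lay within 0.05 of a whole number, as it would if each adjusted p were p times that multiplier over its rank. Under that reading the listed gene with the largest p had rank 3768, so the 158 genes would be 4.19% of the genes at or below that p. The gene 2810403D21Rik would have rank 1124, with 2 listed genes at or below its p, so that most genes with the smallest p-values were not analysed here. A gene not named below was therefore not read as unchanged, and a share of genes higher or lower among all genes was not computed.

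Each gene is described by the ratio of CPM, shRNA over control, with an exact 95% conditional binomial (Clopper-Pearson) interval computed from the raw counts and the library totals. It covers counting error only, and PCR copies of 1 molecule are not independent. With 1 library per group no test between the conditions was possible, and no p-value was computed. The log2 ratio was taken on log2(CPM + 1), which understates the change of genes with few reads. A gene was counted as higher by 2-fold at a log2 ratio of at least 1. The table was used whole, since it holds selected genes. For a control count of 0 no ratio is given, but the lower limit of its exact interval. The interval was tested on simulated data, drawn for the 158 genes at their mean rates in 50 runs per ratio. It covered the true ratio in 97.5% of cases at a ratio of 1, and lay above 1 in 1.32% of them. It lay above 1 in 20.6% of cases at a true ratio of 2, in 52.5% at 4 and in 69.9% at 8. The simulated counts were not selected for a high ratio or a low p, as the listed genes were. These rates are therefore no yardstick for how many listed genes have an interval above 1.

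Symbols were matched by Ensembl identifier for 157 of the 158 genes. The table's positions were identical to those of GENCODE M21, which is on mouse assembly GRCm38, for 134 of these 157 genes and overlapped them on the same strand for all 157. Coordinates below are the table's, counted from 1. Without strand information, reads from overlapping genes on opposite strands cannot be told apart. An exon of another gene on the opposite strand overlapped 40 of the listed genes, and an exon of another gene on the same strand overlapped 5.

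These choices were made before the data were examined: 43 gene lists (pathways, complexes and cell type markers), the rule for named genes and the alternatives below, unless called added. Named genes were members of the lists of nucleosome assembly proteins, RASSF proteins and H3K4 methyltransferase complexes; the 12 highest and the 12 lowest log2 ratios among genes whose mean CPM was at or above the table's median (0.804), leaving out predicted and clone-named genes; and up to 4 members of each list with a mean CPM at or above the 25th percentile (0.459). Ties at the 12th place were kept, which gave 13 genes at the low end. The values of 1 of these 13 are not reported here, and counts over all 27 named genes include it. A median over a list needed 5 listed members, which no list had, so no list median was computed. Alternatives were pseudocounts of 0.1 and 5 CPM, median-ratio and trimmed mean of M values (TMM, edgeR 4.0.16) scaling, a count minimum of 50, a log2 threshold of 1.5, the authors' log2 fold change and an interval that also excludes 1. Added after the data were seen were a count minimum of 10, the count of genes whose interval lay above 1 and the alternatives to it (99% and mid-p intervals, scalings and count minimums). R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.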

Results

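Neural stem cells from the brain of embryonic day 12 mice were infected with lentivirus that carried either the Piscor control construct or Nap1l1-shRNA1, and the RNA of each culture was sequenced. The comparison asks which transcripts differ when an shRNA against Nap1l1 is expressed. There was 1 library per group, with 8777836 reads in the shRNA library and 8325166 in the control, so 1 read equals 0.114 CPM and 0.12 CPM respectively. The 158 genes analysed were all listed by the authors as higher in the shRNA library. They held 2214 reads there and 644 in the control, which is 0.0252% and 0.00774% of each total. Values for Nap1l1 itself were not analysed here, so the level of the targeted gene could not be used to check the labels. No listed gene belonged to the nucleosome assembly protein family, the RASSF family or the H3K4 methyltransferase complexes, and genes lower in the shRNA library were not analysed here.

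Among the named genes, Prdm12 had the most reads in both libraries, and Plxdc1 and Hspa1a had the highest ratios. Prdm12 (ENSMUSG00000079466, chromosome 2, 31640037 to 31655795, plus strand) encodes a PR domain zinc finger regulator of transcription known from sensory neuron development. It had 50 reads in the shRNA library (exact Poisson 95% interval 37.1 to 65.9) and 17 in the control (9.9 to 27.2), or 5.7 and 2.04 CPM, a ratio of 2.79 (exact 95% counting interval 1.58 to 5.16). The authors' deposited table gives it an adjusted p of 0.00165, the smallest of the listed genes. The authors' deposited table marks 19 of the 158 genes as significant, with adjusted p up to 0.0475, and its largest adjusted p is 0.217. Plxdc1 (ENSMUSG00000017417, chromosome 11, 97923238 to 97986444, minus strand), which encodes a plexin domain membrane protein, had 14 reads against 1, a ratio of 13.3 (2.02 to 561). Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156, minus strand), the inducible heat shock protein 70, had 15 reads against 2, a ratio of 7.11 (1.65 to 64.1). Hspa1a has a near-identical copy, Hspa1b, so reads that match both copies may have been left uncounted or given to either one. Cox6a2, the heart and muscle form of a cytochrome c oxidase subunit, had 24 reads against 7, a ratio of 3.25 (1.36 to 8.94). An exon on the opposite strand overlaps each of Prdm12, Hspa1a and Cox6a2, so part of their reads could belong to another gene.

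The listed genes were weakly expressed in both libraries. The highest level was 6.04 CPM, for the long non-coding RNA Gm2824, chosen after its values were seen, with 53 reads in the shRNA library and 22 in the control, a ratio of 2.28 (95% counting interval 1.37 to 3.95). The median gene had 11 reads in the shRNA library and 2 in the control. Of the 158 genes, 39 had no read in the control, and the other 119 had ratios from 2.02 to 14.2 with a median of 3.48. Protein-coding genes made up 83 of the 157 annotated genes. The rest were 35 long non-coding RNAs, 21 loci of the class TEC, which await experimental evidence, 14 pseudogenes and 4 small RNAs.

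**Figure D1:**
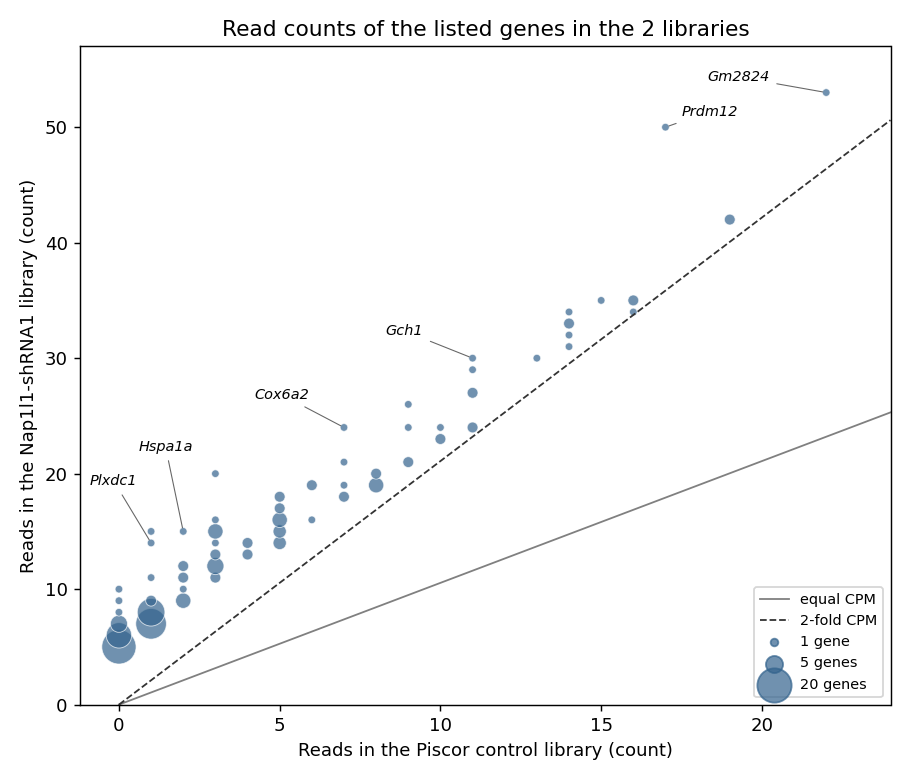
Reads per gene in the Piscor control library (x axis, count) against the Nap1l1-shRNA1 library (y axis, count) for the 158 listed genes. Circle area is proportional to the number of genes at that pair of counts, the solid line marks equal CPM and the dashed line a 2-fold CPM ratio. All genes lie above the dashed line, with 39 at 0 control reads and Gm2824 and Prdm12 at the top with 53 and 50 shRNA reads.

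At this depth 95 of the 158 genes had a counting interval of the ratio wholly above 1, and 63 had an interval that included 1. With a mid-p interval instead of the exact one, added after the data were seen, 155 lay above 1, and with a 99% interval 17 did. The interval lay above 2 for 3 genes: Plxdc1, and, chosen after their values were seen, the non-coding 2810403D21Rik and ENSMUSG00000090286, which had no symbol. The last had 10 reads in the shRNA library and none in the control, with a lower limit of the ratio of 2.13. 2810403D21Rik, which an opposite-strand exon overlaps, had 15 reads against 1, a ratio of 14.2 (2.19 to 599). On log2(CPM + 1), 10 genes were higher by at least 2-fold and 0 were lower; the first count was 155 with a pseudocount of 0.1 CPM, 0 with 5 CPM, 0 under median-ratio scaling, 0 under TMM scaling and 0 at a log2 threshold of 1.5. It was 1 with at least 50 counts, a minimum that only Gm2824 and Prdm12 reach, and 158 by the authors' deposited log2 fold change. The 158 repeats the authors' listing rule, and the 0 lower follows from a list of genes all marked up. Genes were listed for a high ratio and a p under 0.05 in these same libraries. The ratios are thus not independent estimates, and the number of intervals above 1 partly follows from that listing. No replicate shows how much 2 control cultures would differ.

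Within the pool the named genes came from (mean of at least 0.804 CPM, predicted and clone-named genes left out), the remaining 8 of the 12 genes with the highest log2 ratios had ratios between 2.5 and 5.69, each with an interval above 1. Gch1, GTP cyclohydrolase 1, which catalyses the first step of tetrahydrobiopterin synthesis, had 30 reads against 11, a ratio of 2.59 (1.26 to 5.72). Rbm11, a splicing regulator, had 29 reads against 11, a ratio of 2.5 (1.21 to 5.55). Col9a2, a chain of type IX collagen, had 21 reads against 7, a ratio of 2.85 (1.17 to 7.92). Kctd16, an auxiliary subunit of GABA-B receptors, and Fcer2a, the low affinity IgE receptor, each had 19 reads against 6, a ratio of 3 (1.15 to 9.19). Fam129a had 14 reads against 3, a ratio of 4.43 (1.24 to 24). Arl11, a small GTPase of the ARF-like family, and Acad12, of the acyl-CoA dehydrogenase family, each had 12 reads against 2, a ratio of 5.69 (1.27 to 52.4). Of these genes, Kctd16 is overlapped by an opposite-strand exon. Median-ratio and TMM scaling, which centre on the listed genes, each put 20 of the 27 named genes below 0 on the log2 scale. Prdm12 (-0.21 and -0.24), Cox6a2 and Gch1 were among them, and Plxdc1 and Hspa1a lay above 0. All listed genes were marked up, so centring on them puts part of them below 0 by construction. These signs therefore show no direction.

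**Figure D2:**
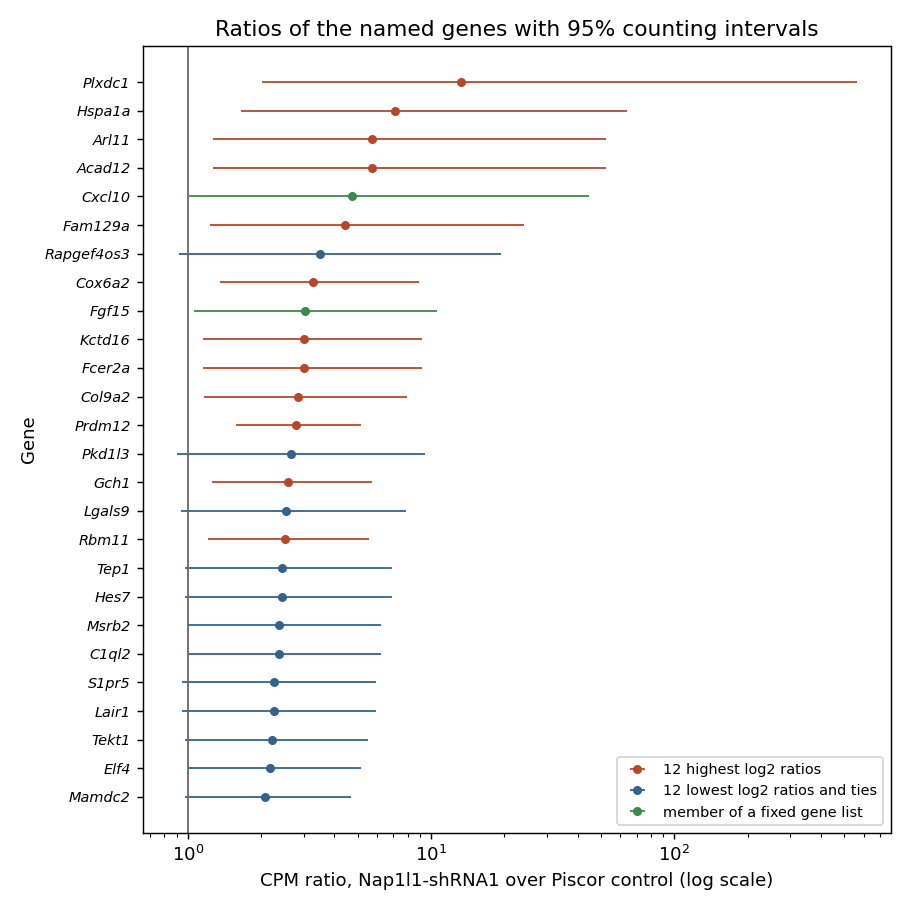
CPM ratio of the Nap1l1-shRNA1 over the Piscor control library (x axis, log scale) for 26 named genes (y axis), with bars for the exact 95% counting interval. Colours mark the 12 highest log2 ratios of the pool, its 12 lowest with ties, and the other members of the fixed gene lists. The first 2 groups were chosen by log2 ratio from the same counts that set the intervals, so their contrast is no finding. Scaling to the listed genes themselves puts 20 of all 27 named genes below 0 on the log2 scale. All listed genes were marked up, so these signs follow from the scaling and show no direction.

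At the low end of the same pool by log2 ratio, 10 of the 12 genes reported had intervals that included 1. Mamdc2 had 24 reads against 11, a ratio of 2.07 (0.976 to 4.68). Tekt1, a tektin of ciliary microtubules, had 21 reads against 9, a ratio of 2.21 (0.972 to 5.49). Hes7, a bHLH repressor known from the segmentation clock, and Tep1, a telomerase-associated protein, each had 18 reads against 7, a ratio of 2.44 (0.972 to 6.91). Elf4, an ETS family transcription factor, had 23 reads against 10, a ratio of 2.18 (0.999 to 5.13). Lair1, an inhibitory receptor of leukocytes, and S1pr5, a sphingosine 1-phosphate receptor, each had 19 reads against 8, a ratio of 2.25 (0.942 to 5.95). Lgals9 (galectin 9) had a ratio of 2.53 (0.94 to 7.89), Pkd1l3 of 2.66 (0.904 to 9.42) and the antisense RNA Rapgef4os3 of 3.48 (0.919 to 19.4). Msrb2, a methionine sulfoxide reductase, and C1ql2, a secreted C1q-like protein, each had 20 reads against 8, and their interval (1.00 to 6.22) just excluded 1. Opposite-strand exons overlap Hes7, Tep1, S1pr5 and Pkd1l3, so part of their reads could belong to other genes.

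Of the 43 gene lists, 3 had a member among the listed genes, 1 gene each, so no list could be described by a median or compared with other genes. From the interferon response list, Cxcl10, an interferon-induced chemokine (chromosome 5, 92346638 to 92348889, minus strand), had 10 reads in the shRNA library and 2 in the control, a ratio of 4.74 (1.01 to 44.5). From the list of FGF, EGF and MAPK feedback genes, Fgf15, a fibroblast growth factor of the embryonic brain (chromosome 7, 144896532 to 144900953, plus strand), had 16 reads against 5, a ratio of 3.03 (1.06 to 10.6). Opposite-strand exons overlap both genes. From the heat shock list, Hspa1a was the 1 listed gene. None of the other lists had a member. They include marker lists of neural stem cell, intermediate progenitor, neuron, interneuron, astrocyte, oligodendrocyte, microglia, endothelial, mesenchymal, erythroid and pluripotent cells and of brain regions, and lists of the cell cycle, p53 targets, apoptosis and the Notch, Wnt and Shh pathways, whose levels were not analysed here.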

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

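The count of intervals above 1, its alternatives and the count with at least 10 counts were chosen after the data were seen. The limits of these results are 1 library per group, the low read counts (the median listed gene had 2 reads in the control) and the table, which holds genes listed for being higher. The count of genes higher by 2-fold was 10 with a pseudocount of 1 CPM. It was 155 with 0.1 CPM, 0 with 5 CPM, 158 by the authors' deposited log2 fold change, 0 at a log2 threshold of 1.5 and 1 with at least 50 counts; the cause of the change with the pseudocount is its size beside levels near 1 CPM. It was 9 with at least 10 counts and 10 where the interval also had to exclude 1. Only Gm2824 and Prdm12 reach 50 counts, and the 1 gene counted there was Prdm12. Under median-ratio scaling the count was 0 and under TMM scaling it was 0. These scalings centre on the listed genes and shift the CPM ratio of all of them by -1.80 and -1.79 on the log2 scale, so by construction they cannot describe a table of genes that are all higher. Under each of them 20 of the 27 named genes lay below 0. The count of genes lower by 2-fold was 0 in every setting run. With library totals this was fixed in advance, since all listed genes were marked up. The 158 by the authors' log2 fold change was likewise fixed by their listing rule. The 95 intervals above 1 became 155 with the mid-p interval, 17 with the 99% interval, 62 with at least 10 counts, 2 with at least 50 counts, 0 with median-ratio scaling and 0 with TMM scaling. With library totals, these numbers partly follow from the listing by p in the same counts. The count minimums also leave fewer genes to count, so their lower numbers do not show a smaller share. Both genes that reach 50 counts, Gm2824 and Prdm12, had an interval above 1. With a pseudocount of 5 CPM the log2 ratios of the 27 named genes ran from 0.22 to 0.60, and 7 of them lay outside their counting interval; no pseudocount can change their sign. Omitting the filter changes nothing, since none was used. Values for Nap1l1 and medians of gene lists could not be recomputed, as there was none to report, and no library could be left out with 1 per group.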

Other observations

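All patterns tested further below were first seen in these data. The test on genes without control reads was moreover chosen after its counts were seen. The genes in this paragraph were chosen after their values were seen. They are single genes and stand for no group, since none of them is in a fixed list and no enrichment was tested. Onecut3, a homeobox transcription factor, had 16 reads in the shRNA library and 5 in the control, a ratio of 3.03 (95% counting interval 1.06 to 10.6), and the transcription factor gene Dmrt3 had 14 against 4, a ratio of 3.32 (1.04 to 13.8). Irx5 had 5 reads against 0, and the interval of its ratio, with a lower limit of 0.869, included 1. The neurotrophin gene Ntf3 had 12 reads against 3, a ratio of 3.79 (1.02 to 20.9). Cyba, a subunit of the NADPH oxidase, had 27 reads against 11, a ratio of 2.33 (1.12 to 5.2). Dock2 had 14 against 4, a ratio of 3.32, and Gbp5, an interferon-inducible GTPase, had 8 against 1, a ratio of 7.59 (1.02 to 337). Ltb, the gene of lymphotoxin beta, had 6 reads against 0, with a lower limit of the ratio of 1.12. Cfap46 had 35 reads against 16, a ratio of 2.07 (1.12 to 4.01). Dnah3, a dynein heavy chain, and Cfap58 each had 7 against 1, and their interval (0.853 to 299) included 1. Opposite-strand exons overlap Dock2 and Dnah3.

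For the 39 genes without a control read, the size of the change depends on which deposited column is read. The authors' deposited table gives them fold changes from 166.5 to 333, while its log2 fold changes correspond to ratios from 9.48 to 19. The exact 95% intervals of their ratios had lower limits from 0.869, for the 20 genes with 5 shRNA reads, to 2.13, and no upper limit. The first column takes 0 as 0.0285 reads and the second as 0.5 reads.

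These 39 genes became fewer as the shRNA count rose, from 20 genes at 5 reads to 11 at 6, 5 at 7 and 1 each at 8, 9 and 10 reads. A candidate explanation is counting noise at low depth. For genes with equal levels each further read on the shRNA side would come with a probability of at most 0.513, the shRNA library's share of all reads, and for a true 2-fold change with 0.678. The observed step-down ratio is the probability of a further read, pooled over the genes at 5 to 10 reads. It was 0.458 (exact 95% interval 0.34 to 0.58), and the interval includes 0.513. This ratio also depends on how many genes have each total count, and would be lower where higher totals are rarer. Those numbers are not known here, nor is it known whether the list holds all genes without a control read. Noise and a change after Nap1l1-shRNA1 thus cannot be told apart for these genes.

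Of the 157 annotated genes, 74 were not protein-coding. Unspliced reads from host genes could place reads on such loci, and then more of them would lie within protein-coding genes than similar loci do. Of the 74, 27 lay inside a protein-coding gene body, against a median of 26 (central 95% of draws 20 to 33) in 10000 draws of annotated genes matched on biotype and length, and 35 overlapped no protein-coding gene at all. No excess inside genes was thus seen. The 35 loci had no annotated protein-coding host, which argues against unspliced reads from within annotated protein-coding genes for those 35. Non-coding host genes were not examined, so they stay open for all 74. For the loci that overlap a protein-coding gene the draws cannot decide, since matching on biotype can take up part of an excess where the biotype depends on position. The draws include loci that these cells do not express, and single loci within introns stay open, as does an effect of the shRNA, which was not tested.

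Fgf15 and the antisense gene Gm26793 (chromosome 7, 144894560 to 144897461, minus strand) were both listed, with 16 reads against 5 and 24 against 9. Their annotated exons share 761 bases, of 3058 in Fgf15 and 2732 in Gm26793. Reads shared between overlapping genes could give both the same ratio, and the Fgf15 ratio was 1.2 times that of Gm26793 (exact 95% interval 0.292 to 5.42). An interval this wide leaves open whether 1 transcript or both were higher, and the 2 genes cannot be told apart from these counts.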
